A study of Mus musculus with 2 samples.

How the data were processed

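Long-read RNA sequencing was done on gastrocnemius tissue of 25-day-old male F1 mice (B6CASTF1/J), with 2 biological replicates in 1 group and 2 µg of RNA per library. Per the labels, the molecule was total RNA and spike-in RNA of the Ambion mix and of a Lexogen set was added; reads on the Ambion (ERCC) spike-ins were found in the count tables, and the Lexogen set was not analysed here. Both labels point to 1 donor record while naming separate animals, so the replicates were taken as separate animals.

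For each library the deposited table gives whole read counts per transcript model, together with the exon number and length of each model, and a deposited annotation gives the coordinates of each model. Per the file headers and the accompanying text, reads were aligned to mm10 and assigned to GENCODE release M21 transcripts or to new models made by TALON, and the 2 libraries were processed separately. The aligner, its version, any read filter and whether assignment used strand are not given in the sources used here. The counts are not normalised, and every listed model has 1 read or more. Each model carries a class: annotated transcript, incomplete splice match (part of an annotated intron chain), unannotated combination of annotated splice sites, chain with a splice site outside the annotation, genomic (an unspliced or partly spliced read over a gene), antisense or intergenic. The length of an annotated model is its length in the annotation, not that of the read. Models with 1 read made up 61.3% of models in replicate 1 and 57.6% in replicate 2. Identifiers of unannotated models are made per library, so these models were matched by chromosome, strand and exact intron chain. Gene positions were taken from the M21 annotation, and coordinates count from 1.

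Reads of all classes were summed per annotated gene, spike-ins left out, and divided by the reads in annotated genes of the library. Total reads were 1292409 in replicate 1 and 1703457 in replicate 2, and reads in annotated genes 1215785 and 1549606. Means and SDs are over the 2 libraries. Shares carry exact 95% Clopper-Pearson intervals, and the limit for a count of 0 rests on 3 counts. Reads are not independent molecules where the library was amplified, so intervals, limits and tests on reads cover counting error only.

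With 1 group there was no test of a condition. Genes with 10 or more reads over both libraries (8692) were compared by a two-sided Fisher exact test of the gene's reads against all other gene-assigned reads, with Benjamini-Hochberg adjustment and a threshold of 0.05; log2 ratios are replicate 2 over replicate 1 of CPM + 1. Fixed lists (11 of muscle and metabolic programmes and 12 of cell type markers) were described by the median log2 ratio and its percentile among 10000 random lists of equal size matched on deciles of mean expression. Isoform use was compared in 48 fixed genes with 20 or more reads per library outside the incomplete and genomic classes, by the share of the transcript with most reads over both libraries. Recurrence was the share of multi-exon unannotated chains with 2 or more reads that had at least 1 read in the other library. The biological coefficient of variation was estimated by edgeR from the 2 libraries with an intercept alone.

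Named genes followed a rule: the 20 with the highest mean CPM, up to 4 members of each list by mean CPM and every myosin heavy chain of the set, the 10 largest differences in each direction past the threshold with 20 or more reads, the 12 isoform genes with most reads and each past the threshold, the 10 unannotated chains with most reads in both libraries, and the 5 antisense or intergenic loci with most reads in both. Lists, tests, this rule and the other settings tried were fixed before the data were examined. Some genes that meet the rule are left out of the text. The text also names other members of these lists, chosen after their values were seen: Cox7a1, Pkm and Gapdh of the metabolic lists, and Myl2, Myl3, Atp2a2, Casq2, Tnni1 and Tnnt3 of the contractile lists. The 8 pairs of fast and slow paralogues, the trend with transcript length and the exon inclusion values were also chosen after the data were seen.

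The settings tried in place of the main ones were read filters, transcript classes, TMM and DESeq2 scaling, fixed coefficients of variation of 0.2 and 0.4 in edgeR's exact test, pseudocounts of 0.1 and 10, isoform and recurrence minimums, matching of splice sites within 5 bp, mitochondrial and single-exon reads, and leaving out each library. Matching random lists on transcript length, and taking the class of a chain from either library, were added after the data were seen. Genes without reads on an annotated transcript had no such length and were left out of that matching. The methods were tested on simulated data. On counts for 8646 genes drawn with counting error alone from the pooled shares and depths of the 2 libraries, so without spread between animals, the gene test called 0.0710% of unchanged genes and recovered 44.0% of genes changed 2-fold and 70% of those changed 4-fold. In edgeR's exact test of the same comparison on 8692 simulated genes, 76.8% of 4-fold changes with 100 or more reads were recovered at a coefficient of 0.2 and 0% at 0.4. Of 40 simulated lists without change 7.5% lay outside the central 95% of random lists, and a list raised by 1 on the log2 scale lay at percentile 100.

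Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, blastn 2.17.0, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0 were used. Spike-ins were left out of gene levels, alleles of the 2 parental strains were not separated, and reads outside annotated genes entered the class shares and the antisense and intergenic loci alone.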

Results

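RNA of the mouse gastrocnemius, a calf muscle made mainly of fast fibres, was sequenced in long reads, each of which was assigned to a transcript model. The tissue came from 25-day-old male F1 mice of the cross between the inbred strains C57BL/6J and CAST/EiJ. The series holds 1 group with 2 biological replicates, described by the labels as separate animals, and 2 µg of RNA went into each library. Replicate 1 held 1292409 reads and replicate 2 held 1703457, of which 1240942 and 1654197 lay on mouse transcript models and the rest on spike-in RNA. Reads in annotated genes numbered 1215785 and 1549606, and they detected 13389 genes in replicate 1 and 14122 in replicate 2, with 11889 found in both. Levels are given as CPM, the reads of a gene per 1000000 reads in annotated genes of the library. A count of 0 allowed a level of up to 2.47 CPM in replicate 1 and 1.94 CPM in replicate 2. With 1 group there is no comparison between conditions: the values below describe what this muscle expressed, and every test between the libraries compares these 2 libraries, not conditions.

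Genes of fast contraction, calcium uptake and energy supply led the transcriptome. Atp2a1, the calcium pump of the fast-fibre sarcoplasmic reticulum, had the highest mean level, 87526 ± 90495 CPM (SD, n = 2), but its level in replicate 1, 151516 CPM, was 6.44 times the 23536 CPM in replicate 2. Ckm, muscle creatine kinase, was steadier at 69061 ± 485 CPM, as was skeletal alpha-actin (Acta1) at 68659 ± 3787 CPM. Fast troponin C (Tnnc2) reached 36930 ± 18251 CPM, alpha-tropomyosin (Tpm1) 26883 ± 2589 CPM, the fast regulatory light chain Mylpf 25458 ± 9126 CPM and the alkali light chain Myl1 20907 ± 9036 CPM. Myosin heavy chain 2B (Myh4) stood at 16849 ± 9925 CPM. The glycolytic enzymes Aldoa, Eno3, Ldha and Pgam2 had 14265 ± 818, 9148 ± 1522, 7401 ± 229 and 5579 ± 2613 CPM. The mitochondrial ADP/ATP carrier Slc25a4 had 14029 ± 6258 CPM, cytochrome oxidase subunit Cox4i1 5927 ± 4164 CPM and ATP synthase subunit Atp5b 5881 ± 2651 CPM. Fast alpha-actinin (Actn3), calsequestrin 1 (Casq1), adenylate kinase (Ak1), fast troponin I (Tnni2) and the titin cap Tcap completed the 20 most abundant genes, with 6375 ± 4578, 6038 ± 1915, 5189 ± 942, 5028 ± 1099 and 4517 ± 989 CPM. The 10 most abundant genes held 42.2% of gene-assigned reads in replicate 1 and 33.9% in replicate 2.

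Which fibre types the muscle held was read from the share of each heavy chain among the reads of 6 myosin heavy chain genes. Myh4, the chain of the fastest 2B fibres, made up 77.0% of them in replicate 1 (95% Clopper-Pearson interval 76.6 to 77.4, 37680 reads) and 88.1% in replicate 2 (87.6 to 88.6, 17286 reads), a mean of 82.6% ± 7.86 (SD, n = 2). Myh1, the 2X chain, held 16.4% and 6.98%, Myh2, the 2A chain, 3.29% and 2.45%, and Myh7, the slow chain, 3.23% and 2.42%. Embryonic Myh3 had 13 reads in replicate 1 and 3 in replicate 2, and perinatal Myh8 had 4 and 1, shares of 0.0345% and 0.0174% for Myh3 and of 0.0106% and 0.00579% for Myh8. Myh4 and Myh1 ranked first and second in both libraries, while Myh2 and Myh7 had overlapping intervals (1241 and 1216 reads in replicate 1, 423 and 418 in replicate 2). The share of Myh4 differed between the libraries by the two-sided Fisher exact test (p = 7.3e-220 over reads). Over annotated transcripts alone the direction turned, with Myh4 at 55.6% in replicate 1 and 51.01% in replicate 2 (mean 53.3%, two-sided Fisher exact p = 0.0039), and Myh7 (mean 9.90%) lay above Myh2 (4.92%). Without incomplete splice matches and genomic reads Myh4 was at 56.8% and 69.4% (mean 63.1%), but the libraries gave the same Myh4 chains different class labels. With the class of a chain taken from either library it was at 75.5% and 69.4% (mean 72.4%, exact p = 3.3e-09), so the direction turned there too. All intervals and tests on reads cover counting error only.

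**Figure D1:**
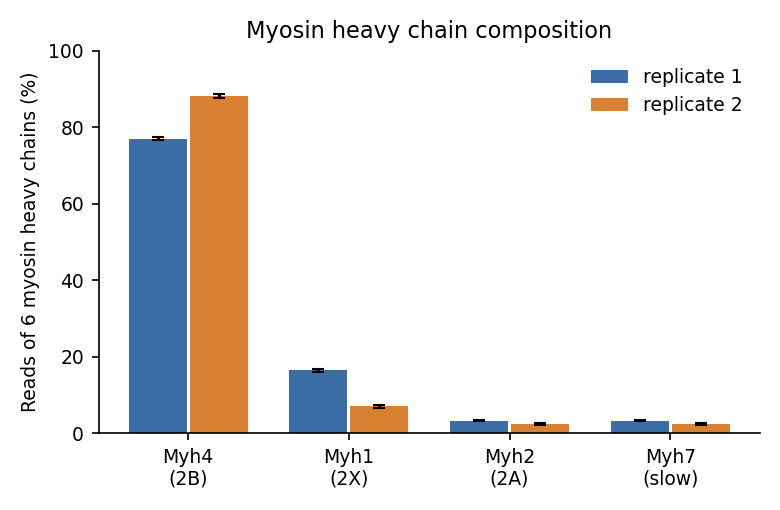
Share of reads, in percent of the reads on 6 myosin heavy chain genes, of Myh4, Myh1, Myh2 and Myh7 in the 2 gastrocnemius libraries, with error bars for 95% Clopper-Pearson intervals; Myh3 and Myh8, both under 0.04%, are not drawn. Myh4 took 77.0% in replicate 1 and 88.1% in replicate 2.

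Fast sarcomere genes stood above their slow counterparts in sum and in 7 of 8 pairs of paralogues in both libraries. The 14 genes of the fast list summed to 288732 ± 77112 CPM and the 11 genes of the slow list to 7143 ± 3089 CPM (n = 2), a ratio of 69.2 in replicate 1 and 25.1 in replicate 2 (log2 5.38 ± 1.03). Over annotated transcripts alone the log2 was 5.74 ± 0.09, a setting that leaves out the main Atp2a1 transcript and with it 95.2% and 87.6% of the reads of that gene. Between paralogues, the ratio of the fast to the slow gene in replicates 1 and 2 was 23.9 and 36.4 for Myh4 over Myh7, 210 and 92.1 for Mylpf over Myl2, and 77.1 and 40.03 for Tnnc2 over Tnnc1. It was 37.4 and 20.97 for Tnni2 over Tnni1, 522 and 238 for Atp2a1 over Atp2a2, 98.8 and 102 for Casq1 over Casq2, and 4.13 and 5.64 for Mybpc2 over Mybpc1. Troponin T was the exception among these 8 pairs, with Tnnt3 at 3.42 times Tnnt1 in replicate 1 and 0.799 times in replicate 2. Outside the incomplete and genomic classes the ratio of Tnnt3 over Tnnt1 was 20.2 and 15.9, so the exception rests on incomplete and genomic reads of Tnnt1. That of Myh4 over Myh7 was 7.70 and 8.50, or 18.1 and 8.50 with the class of a chain taken from either library. Within the slow list Tnnt1 had 575 and 4897 CPM, slow myosin-binding protein C (Mybpc1) 1722 and 318 CPM, Tpm3 515 and 1173 CPM, and cardiac and slow troponin C (Tnnc1) 312 and 1245 CPM.

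Other muscle programmes were present at graded levels. Glycolysis and creatine genes summed to 116681 ± 230 CPM over 14 genes, and nuclear genes of oxidative metabolism to 42936 ± 19642 CPM over 16, led by Slc25a4, Cox4i1, Atp5b and Cox6a2 (2788 ± 2030 CPM). Thin-filament and Z-disc genes summed to 45677 ± 3171 CPM over 12, with desmin (Des) at 3260 ± 102 CPM and Tpm2 at 3236 ± 20.1 CPM beside Tpm1 and Tcap. Genes of giant and membrane-associated proteins summed to 2847 ± 886 CPM over 12, led by the calcium release channel Ryr1 (628 ± 231 CPM), Cacna1s (587 ± 308), Xirp2 (374 ± 231) and Nrap (342 ± 260). Over annotated transcripts alone this sum was 609 CPM, with 1148 in replicate 1 and 70.4 in replicate 2. The developmental list reached 1214 ± 98.3 CPM over 10 genes, nearly all of it cardiac actin (Actc1, 629 ± 120) and the imprinted RNA H19 (531 ± 14.7), with Myl4 at 21.1 ± 15.8 and Igf2 at 13.7 ± 0.733 CPM. Growth and atrophy genes summed to 660 ± 109 CPM over 12, with the ubiquitin ligase Trim63 at 277 ± 112, Eif4ebp1 at 107 ± 30.3, Mettl21c at 100.01 ± 61.2 and Fbxo32 at 62.7 ± 26.5 CPM. Clock genes reached 243 ± 91.6 CPM over 10, led by Tef (97.9 ± 58.1), Nr1d1 (66.3 ± 6.57), Nr1d2 (24.5 ± 16.5) and Arntl (22.3 ± 11.5). Immediate early and stress genes reached 438 ± 8.14 CPM over 13 detected of 14, led by the small heat shock proteins Hspb1 (173 ± 31.2) and Hspb7 (93.9 ± 3.25), metallothionein Mt1 (58.0 ± 23.9) and Jun (33.4 ± 19.01). Gapdh, a member of the glycolytic list, had 44.4 and 72.9 CPM, while 23 near-identical annotated copies held 6620 and 5593 reads.

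Markers of other cells were few beside the muscle genes. Fibroblast markers had the highest mean of the 12 cell type lists, 3751 ± 3361 CPM, carried by replicate 1 (6128 CPM, against 1375 in replicate 2). They were led by Col1a1 at 2448 and 279 CPM, Gsn at 1535 and 452, Col3a1 at 1387 and 237, and Col1a2 at 449 and 194 in replicates 1 and 2. The adipocyte list, the most abundant in replicate 2, reached 3198 ± 49.9 CPM, but Car3, which muscle fibres also express, made up 3177 ± 49.8 of it, while Cfd had 14.2 ± 0.886, Adipoq 2.20 ± 0.376 and Plin1 2.11 ± 0.662 CPM. Haemoglobin and other erythroid genes reached 516 ± 174 CPM, with Hba-a1 at 267 ± 84.8, Hbb-bs at 147 ± 45.4, Hba-a2 at 73.6 ± 31.9 and Hbb-bt at 25.0 ± 12.1; the near-identical globin copies can share reads, so the split between them is uncertain. Schwann cell markers reached 331 ± 254 CPM with Pmp22 at 140 ± 75.4, Mbp at 54.5 ± 22.4 and S100b at 4.78 ± 3.27. The tendon list stood at 252 ± 64.1 CPM (Fmod 86.1 ± 67.9, Thbs4 71.3 ± 3.16, Scx 31.8 ± 13.5, Chad 23.4 ± 11.1) and the endothelial list at 209 ± 41.5 (Fabp4 119 ± 79.9, Cav1 52.0 ± 20.6, Tie1 11.9 ± 7.65, Pecam1 7.84 ± 2.87), or 129 over annotated transcripts alone. Neuromuscular junction genes summed to 197 ± 42.9 CPM (Prkar1a 125 ± 43.8, Chrna1 23.5 ± 0.439, Chrne 22.0 ± 4.42, Colq 10.6 ± 1.30), smooth muscle and pericyte genes to 164 ± 35.1 (Rgs5 86.4 ± 51.1, Acta2 36.8 ± 18.3, Tagln 14.6 ± 3.14, Pdgfrb 10.3 ± 6.36), and immune genes to 78.8 ± 0.874 (Lyz2 27.9 ± 1.19, C1qa 18.1 ± 0.0185, Cd74 13.4 ± 0.277, C1qb 10.2 ± 2.85). Satellite cell genes reached 53.5 ± 8.11 CPM, led by Myod1 (22.1 ± 4.80), Chodl (20.0 ± 10.1), Sdc4 (7.78 ± 6.34) and Vcam1 (1.06 ± 0.331). Cardiac and keratinocyte markers were near the limit of detection, at 9.01 ± 4.60 and 10.4 ± 5.39 CPM (3.99 for the keratinocyte list over annotated transcripts alone), with Sln (2 and 17 reads), Myh6 (4 and 2), Tnni3 (1 and 0), Krt10 (5 and 21), Perp (3 and 0) and Krtdap (0 and 1).

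Genes with short transcripts were mostly higher in replicate 2, and genes with long transcripts were lower more often than higher. Cox7a1, Cox6a2 and Cox4i1 stood at log2 ratios of 2.17, 1.64 and 1.57 (replicate 2 over replicate 1), and mt-Cytb at 3.10, while Col1a1 stood at -3.13, Myh1 at -2.71, Atp2a1 at -2.69 and Mybpc1 at -2.43. Of 8692 genes with 10 or more reads, 3766 differed between the 2 libraries (two-sided Fisher exact test, Benjamini-Hochberg adjusted p under 0.05), 1480 higher and 2286 lower in replicate 2, and 2780 of the 3766 by over 2-fold. Scaled by edgeR's TMM, the split was 1953 higher and 1600 lower, and by DESeq2's size factors 1995 and 1540. The median log2 ratio of all tested genes was -0.27, and TMM scaling raised the ratios by 0.29, so that values of this size below 0 follow the bulk of genes; Acta1 (-0.11 ± 0.01, counting SE) and Aldoa (-0.12 ± 0.01) became higher in replicate 2 under both scalings. Across genes, which are not independent replicates, log2(CPM + 1) of the libraries correlated at Pearson r = 0.824 and Spearman rho = 0.779, 60.0% of tested genes lay within 2-fold, and the common biological coefficient of variation estimated by edgeR was 0.503. With a coefficient of 0.4 in place of counting error alone, edgeR's exact test called 8 genes, and with 0.2 it called 1345.

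Most genes with the largest ratios had few reads or reads of genomic or incomplete models. Among genes past the threshold with 20 or more reads, those lowest in replicate 2 included the pseudogenes Vcp-rs (71 reads in replicate 1 and 0 in replicate 2) and Oaz1-ps (66 and 1), the interferon-induced GTPase Iigp1 (28 and 1), Atp9b (26 and 1), Cep85l (36 and 2), Acbd3 (35 and 2), Ckap5 (30 and 2), Ppfibp1 (46 and 4) and Stat5a (20 and 1). The 10 highest in replicate 2 were Usp50 (0 and 696), Gm6829 (0 and 185), Gm45233 (0 and 65), Gm29253 (0 and 57), Gm15935 (0 and 45), AC154200.1 (7 and 195), Gm15932 (0 and 26), Gm6563 (4 and 105), Gm45692 (17 and 311) and Egr2 (1 and 36). In 9 of these 10 higher genes over 50% of the replicate 2 reads were genomic or incomplete models, against 0 of the 10 lowest in replicate 1. The exception was Gm6563, a processed pseudogene, with 103 of 105 replicate 2 reads on its annotated model. For Usp50, 692 of 696 reads formed a single-exon model at chromosome 2, 126709096 to 126709354. Some counts rest on reads outside the gene. All 36 Egr2 reads of replicate 2 lay at chromosome 10, 67542188 to 67547498, while Egr2 ends at 67542188. In Gm6829, 183 of 185 reads lay at chromosome X, 9328974 to 9332622, and the gene ends at 9328108. In Iigp1, 18 of 28 replicate 1 reads lay at chromosome 18, 60439318 to 60443848, and the gene ends at 60392634. These counts thus do not show a difference of the 3 genes themselves. The reads of AC154200.1 lay at chromosome 17, 17345177 to 17345456, next to the Oaz1-ps model at 17345456 to 17346140. Gm15932 and Gm15935 are annotated as antisense genes, and whether reads were assigned by strand is not given in the sources used here, so their counts are uncertain.

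Mitochondrially encoded genes moved as a block. All 11 tested of 12 were higher in replicate 2, as they were under TMM and DESeq2 scaling, with mt-Cytb at 353 and 3039 CPM, mt-Co1 at 653 and 1948, mt-Nd1 at 118 and 527, and mt-Nd2 at 124 and 422. Their median log2 ratio of 2.14 lay above all of 10000 random lists of equal size and like expression, and all reads on the mitochondrial chromosome, those outside the list included, took 0.160% of mouse reads in replicate 1 and 0.731% in replicate 2. The 16 nuclear genes of oxidative metabolism split into 11 higher, 2 lower and 3 not past the threshold (median 1.02, percentile 94.8), with Slc25a4 at 0.94 and Cox6a2 at 1.64. Atp5b, at 0.95 over all classes, was at -0.63 over annotated transcripts alone.

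Contractile lists were mixed. The fast list had 6 genes higher and 8 lower of 14 (median -0.39, percentile 4.11): Tnnc2 (1.05), Mylpf (0.75) and Tnni2 (0.45) were higher and Myh4 (-1.28), Actn3 (-1.61), Casq1 (-0.66) and Mybpc2 (-1.99) lower. The slow list had 6 higher and 4 lower of 10 tested (median 1.23, percentile 98.3). Tnnt1 (3.09, or 1.11 without incomplete and genomic reads), Tnnc1 (1.99), Myl2 (1.93), Myl3 (1.31) and Tpm3 (1.19) were higher, while Mybpc1 (-2.43), Myh7 (-1.89), Atp2a2 (-1.55) and Casq2 (-0.70) were lower. The percentile of the slow list was 41.5 over annotated transcripts alone and 48.6 against random lists matched on transcript length too. The latter held 8 of the 10 genes, without Tnnt1 and Tnni1, and their median was 0.25. Of 12 genes of giant and membrane proteins 2 were higher, 9 lower and 1 not past the threshold (median -0.90, percentile 0.85), with Nrap at -1.73, Cacna1s at -1.12 and Ryr1 at -0.76 (without incomplete and genomic reads -0.23 and not past the threshold, or -0.95 and past it with the class of a chain taken from either library) but Xirp2 at 1.35. With random lists matched on transcript length too, 8 of the 12 genes remained and the list lay at percentile 34.6, inside the central 95%. Of 12 thin-filament and Z-disc genes 6 were higher, 3 lower and 3 not past (median 0.10, percentile 27.9), or 7 higher and 3 lower adjusted over the list alone, and 9 higher and 2 lower under TMM and DESeq2 scaling. Tpm1 stood at 0.20 and Tcap at 0.45. Of 14 glycolysis and creatine genes 4 were higher, 7 lower and 3 not past (median -0.09, percentile 16.1), or 5 higher and 7 lower adjusted over the list alone, and 8 higher and 6 lower under TMM and DESeq2 scaling. Eno3 (0.34) and Ldha (0.06) were higher in that list and Pkm (-0.97) and Pygm (-1.37) lower, while Ckm was at 0.01 ± 0.01 (counting SE) and not past the threshold. Ckm did pass it with 20 or more reads per gene, without mitochondrial genes (0.02), without incomplete and genomic reads (0.16) and under TMM (0.31) and DESeq2 scaling (0.33), and with the other sign over annotated transcripts (-0.13).

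Growth and clock genes had more members lower than higher in replicate 2. Of 10 tested growth and atrophy genes 2 were higher, 6 lower and 2 not past (median -0.86, percentile 6.84, or 2.24 with a pseudocount of 10), with Trim63 at -0.85 and Fbxo32 at -0.88 but Mettl21c at 1.32 and Eif4ebp1 at 0.58. Of 7 tested clock genes 4 were lower and 3 not past, with Tef at -1.28, Nr1d2 at -1.42 and Arntl at -1.05. The median was -1.05, at percentile 7.27, or 2.09 over annotated transcripts and 23.2 matched on transcript length too. The difference of Arntl ended under TMM scaling, which left 3 lower, and DESeq2 scaling gave 1 higher and 3 lower. Immediate early and stress genes had 2 higher (Hspb1 0.37, lost over annotated transcripts, Mt1 0.85), 3 lower (Jun -1.19 among them) and 5 not past of 10 (percentile 42.7). The developmental list had 1 higher (Myl4, 1.61), 2 lower and 4 not past of 7 (percentile 64.8); Actc1 was at -0.39 and lost its difference under TMM, and H19 and Igf2 were not past the threshold. Myl4 lost its difference over annotated transcripts (0.88) and without incomplete and genomic reads (1.26). Under TMM and DESeq2 scaling the list had 2 higher and 1 lower, with H19 past the threshold at 0.35 and 0.37.

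Fibroblast markers were low and Schwann cell markers high among random lists matched on expression, but neither place held under every setting. Of 7 fibroblast genes 5 were lower and 2 not past (median -1.20, percentile 0.80, or 9.78 matched on transcript length too), with Col1a1 at -3.13, Col3a1 at -2.54, Gsn at -1.76 and Col1a2 at -1.20, and of 6 tested Schwann cell genes 3 were higher and 3 not past (median 1.19, percentile 98.7, or 88.5 over annotated transcripts), with Pmp22 at 1.15 and Mbp at 0.85. Over annotated transcripts alone Pmp22 was at 0.06 and Mbp at 0.24, neither past the threshold. All 4 tested erythroid genes were higher (median 0.78, percentile 85.4, but 5.63 matched on transcript length too). Hbb-bs (0.27) and Hbb-bt (0.49) were no longer past the threshold over annotated transcripts, nor was Hbb-bt (0.70) without incomplete and genomic reads. Also higher were Sln of the cardiac and Krt10 of the keratinocyte list, the single members tested there. Satellite cell genes had 1 higher (Sdc4), 1 lower (Chodl) and 1 not past of 3 (percentile 49.7). Neuromuscular junction genes had 2 lower, Prkar1a among them, and 5 not past of 7 (percentile 73.4), and tendon genes 1 higher (Scx), 2 lower (Fmod and Chad) and 3 not past of 6 (percentile 53.8). Endothelial genes had 1 higher (Fabp4), 2 lower (Cav1 and Tie1) and 4 not past of 7 (percentile 26.6). Smooth muscle and pericyte genes had 2 higher (Acta2 among them), 3 lower (Rgs5 and Pdgfrb among them) and 1 not past of 6 (percentile 46.2), and none of 5 immune or 2 adipocyte genes passed. Chodl, Chad, Cav1, Tie1 and Pdgfrb lost their differences under TMM and DESeq2 scaling. The counts adjusted over the list alone equalled those over all genes in every list but the 2 named for the thin filament and glycolysis. In all, 5 of 20 lists with 3 or more tested genes lay outside the central 95% of random lists. Under TMM and DESeq2 scaling the medians of the glycolysis (-0.09), neuromuscular junction (-0.04), tendon (-0.21) and immune (-0.00) lists became positive.

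The difference followed transcript length in the mouse genes and in the spike-ins. The median log2 ratio was 1.33 for 331 genes whose main annotated transcript was under 600 nt, 0.94 for 637 genes of 600 to 1000 nt, 0.24 for 2066 genes of 1000 to 2000 nt, -0.64 for 3283 genes of 2000 to 4000 nt and -1.04 for 1890 genes of 4000 nt or more. Across the 8207 genes with such a length, Spearman's rho of length and log2 ratio was -0.594. Spike-in RNA took 3.98% of all reads in replicate 1 and 2.89% in replicate 2. Over the 20 spike-ins with 100 or more reads, between 505 and 1124 nt long, rho of length and log2 share ratio was -0.768 (permutation p = 0.00016) and Pearson's r -0.878; the 6 under 600 nt had a median of 0.45 and the 11 over 900 nt a median of -0.52.

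**Figure D2:**
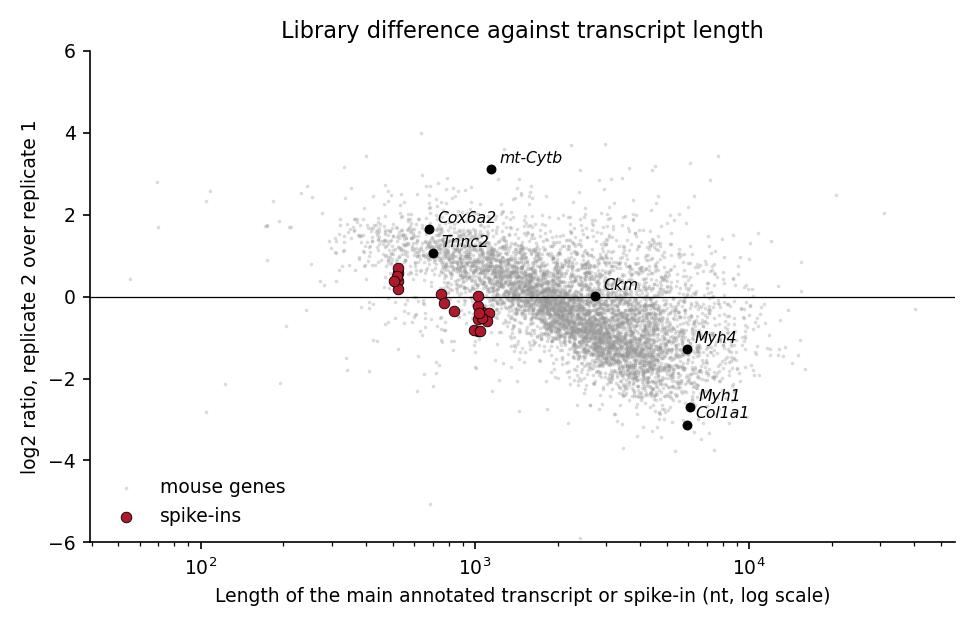
Log2 ratio of replicate 2 over replicate 1 (vertical axis) against the length in nt of the main annotated transcript or spike-in (log scale), with each grey point a tested mouse gene, each red point 1 of the 20 spike-ins and 7 genes marked by name. Both fall with length, from a median of 1.33 in mouse genes under 600 nt to -1.04 at 4000 nt or more.

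Reads on annotated transcripts formed the largest class in both libraries, 64.5% of mouse reads in replicate 1 and 66.1% in replicate 2 (65.3% ± 1.16, SD, n = 2). Chains with a splice site outside the annotation held 16.9% and 4.03%, 175352 and 31937 of those reads on a single Atp2a1 transcript, and unannotated combinations of annotated splice sites held 5.23% and 2.48%. Incomplete splice matches, which carry part of an annotated chain, held 9.10% and 14.7%. Genomic reads held 2.28% and 6.52%, antisense reads 1.70% and 5.21% and intergenic reads 0.271% and 0.959%, and single-exon models made up 98.1% and 99.1% of the genomic reads. Every 95% Clopper-Pearson interval was narrower than 0.2 points. Part of the difference between the libraries lies in labels: 1181 shared intron chains, with 36686 and 27251 reads, carried another class in each library. The median length of the model behind a read was 2124 nt in replicate 1 and 1125 nt in replicate 2. Incomplete splice matches took 6.25% and 9.59% of reads in genes with main transcripts under 1000 nt, and 14.5% and 20.5% in genes of 2000 nt or more. Genomic reads took 1.27% and 2.47% in the shorter genes and 3.11% and 12.0% in the longer ones.

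**Figure D3:**
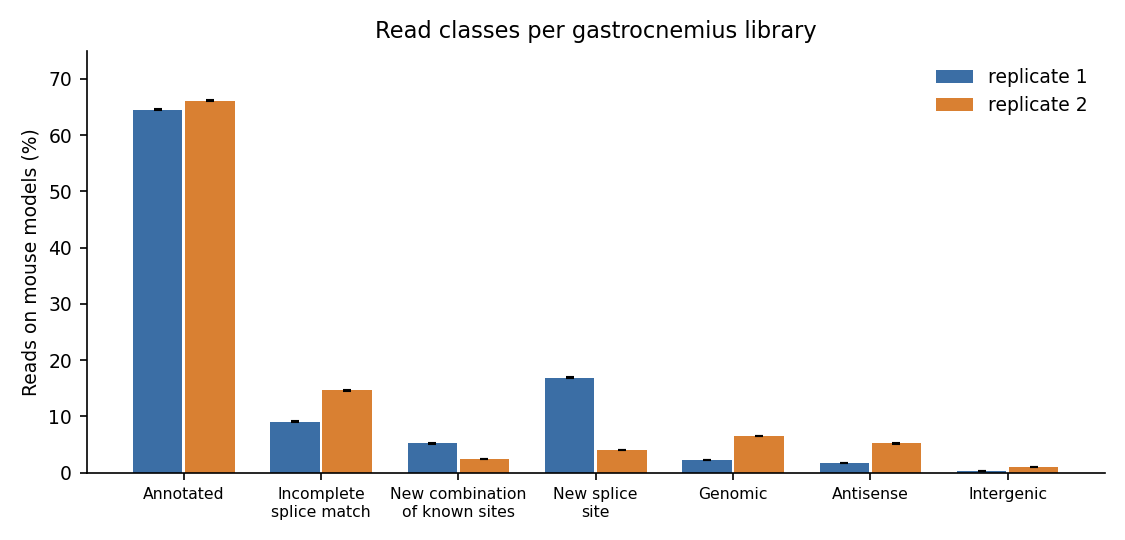
Percent of reads on mouse transcript models in each of 7 classes, for the 2 gastrocnemius libraries, with error bars for 95% Clopper-Pearson intervals. Annotated transcripts held 64.5% and 66.1%, and chains with a new splice site 16.9% in replicate 1 against 4.03% in replicate 2.

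Most abundant muscle genes were read from 1 dominant transcript. Among reads outside the incomplete and genomic classes, the main annotated transcript held 99.4% of Ckm in both libraries, 98.9% and 98.8% of Acta1, 98.7% and 98.5% of Tpm1, 99.5% and 99.1% of Mylpf, and 96.3% and 96.4% of Tpm2. Myl1 and Eno3 were split, with the main transcript at 68.2% and 71.9% in Myl1 and at 56.3% and 59.3% in Eno3. The main transcript of Atp2a1 was unannotated and held 98.0% and 97.1%. Over 40 of 48 fixed genes with 20 or more such reads in each library, the main transcript held a median of 74.7% of reads (80.4% in replicate 1 and 71.7% in replicate 2), and it was unannotated in 14 of them. The shares differed by a median of 3.83 points, and 15 genes passed the two-sided Fisher exact test adjusted over the 40. Past the threshold with smaller differences were Atp2a1, Tpm1, Mylpf, Myl1, Eno3, Actn3 (95.6% and 91.5%), Mybpc2 (96.1% and 94.5%), Pygm (97.2% and 93.2%), Pdlim3 (88.1% and 80.7%) and Myh1 (78.9% and 70.5%); Myh2 (73.0% and 54.0%) followed on 652 and 63 reads. In the other 4, Aldoa, Pdlim7, Myh4 and Trdn, the libraries gave some shared intron chains different class labels. With the class taken from either library, the main chain held 91.3% and 89.5% in Aldoa and 90.9% and 89.5% in Pdlim7. Pdlim7 was then no longer past the threshold (adjusted p = 0.536, Fisher exact test). In Myh4 and Trdn another chain became the main one, at 57.4% and 51.2% in Myh4 and at 24.4% and 9.92% in Trdn. The first main chain had held 76.7% and 34.1% in Myh4 and 6.82% and 20.5% in Trdn. Whether labels caused the difference of that first Trdn chain was not tested.

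Most unannotated splice chains with 2 or more reads were found again in the other animal. Of the unannotated combinations of annotated sites with 2 or more reads, 58.9% of 3731 in replicate 1 were found in replicate 2 (95% interval 57.3 to 60.4) and 74.4% of 2625 in replicate 2 were found in replicate 1 (72.6 to 76.0). For chains with a splice site outside the annotation the values were 59.5% of 2833 (57.7 to 61.3) and 61.5% of 2810 (59.7 to 63.3). Annotated chains recurred at 86.1% and 92.5%. The classes did not differ from replicate 1 to 2 (two-sided Fisher exact p = 0.595) and did from 2 to 1 (p = 4.2e-24). Both calls turned with splice sites matched within 5 bp (exact p = 2.6e-05 and 0.106), and with 1 or more reads both directions differed (exact p = 1.8e-52 and 2.7e-167).

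The 10 unannotated chains with most reads in both libraries lay in 9 genes, led by Atp2a1. On mm10, the leading Atp2a1 chain (chromosome 7, minus strand, 126445858 to 126463108, 22 exons) had 175352 and 31937 reads; against the nearest annotated transcript it lacked the 18-nt exon at 126462500 to 126462517 and used a new intron from 126462188 to 126462778. In Tnni2 a 7-exon chain (chromosome 7, 142441808 to 142444410) held 4054 and 5462 reads, 78.4% and 60.7% of the gene, with a new intron from 142442499 to 142443170. A 5-exon Oaz1 chain had 1405 and 2883 reads and differed from the nearest annotated transcript by lacking its 4-base annotated gap at chromosome 10, 80828292 to 80828295. In Srl, 1990 and 516 reads used an intron from 4493881 to 4522992 on chromosome 16, whose start is 3 bases from the annotated one at 4493878, and in Ndrg2 991 and 696 reads joined 51911547 to 51913923 on chromosome 14. The Idh3b chain (529 and 843 reads) had a new intron from 130279438 to 130280262 on chromosome 2, the Vdac3 chain (497 and 839) one from 22583737 to 22587548 on chromosome 8, and the Mrpl33 chain (256 and 900) one from 31614031 to 31616380 on chromosome 5. Myl1 had 2, an 8-exon chain of 419 and 1021 reads and a 6-exon chain of 190 and 936 reads that lacked the 28-nt exon at 66934246 to 66934273 on chromosome 1. The lack of the Atp2a1 exon belonged to a wider pattern of short exons: of 146 coding exons of 25 nt or less, 29.5% were missing from most spanning reads of both libraries through an unannotated intron, against 0.0617% of 17819 exons over 50 nt.

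**Figure D4:**
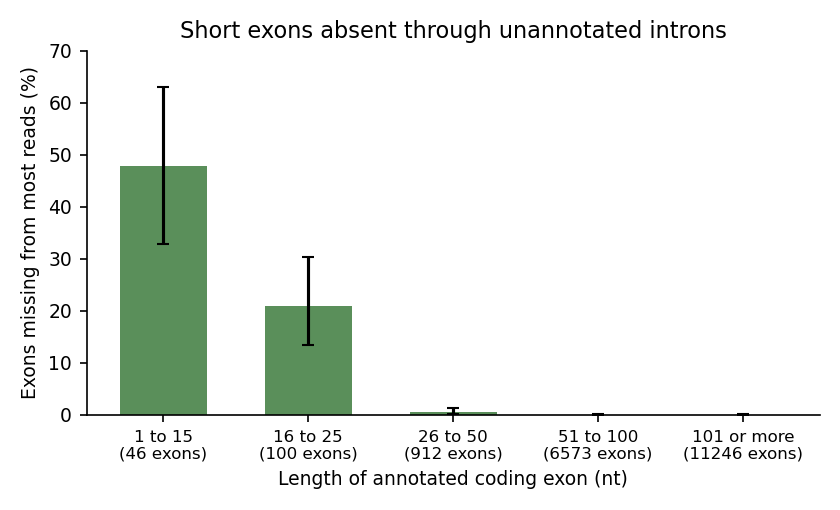
Percent of annotated internal coding exons, by exon length in nt, that were missing through an unannotated intron from over 50% of spanning reads in both libraries; each bar is a length class with its number of exons, and error bars are 95% Clopper-Pearson intervals. The share is 47.8% at 1 to 15 nt and 21% at 16 to 25 nt, and below 1% in the longer classes.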

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

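The loci below were picked out because they lie outside annotated genes on their strand, and so outside every comparison of the report, and because their level exceeds the limit that a count of 0 allows, 2.42 reads per 1000000 mouse reads in replicate 1 and 1.81 in replicate 2. The series has no control samples, and none of the loci was tested for a cause.

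Antisense to Klhl31, a gene of striated muscle, the locus on the minus strand of chromosome 9 from 77656560 to 77660127 held 2370 reads in replicate 1 and 10394 in replicate 2, a mean of 4097 ± 3093 reads per 1000000 mouse reads (SD, n = 2). On chromosome 17, minus strand, 39843013 to 39846245, opposite the long noncoding gene Gm26917 and within 2 kb of an annotated ribosomal RNA, 1747 and 369 reads gave a mean of 815 ± 838. The other loci were antisense to Cdv3 (chromosome 9, plus strand, 103354029 to 103355313; 229 and 1877 reads, mean 660 ± 672), to Ptp4a2 (chromosome 4, minus strand, 129837040 to 129840766; 153 and 1224 reads, mean 432 ± 436) and to Msrb3 (chromosome 10, plus strand, 120781473 to 120783314; 104 and 1225 reads, mean 412 ± 464). In all 5611 antisense or intergenic loci were found in both libraries. Whether reads were assigned by strand is not given in the sources used here, so reads of Klhl31, Cdv3, Ptp4a2 and Msrb3 cannot be separated from those of their antisense loci.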

How the results depend on the processing

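Settings were chosen before the data were examined, except that matching lists on transcript length and taking chain classes from either library were chosen after the results were seen. The count of genes that differed stayed within 1.5 times 3766 under other read filters, transcript classes and scalings (3292 to 3754), but fell to 1345 with a fixed coefficient of variation of 0.2 and to 8 with 0.4, since both add spread between animals. The sign turned for Acta1 without incomplete and genomic reads (0.0389), under TMM (0.18) and under DESeq2 scaling (0.20), for Aldoa over annotated transcripts (0.0155), under TMM (0.18) and under DESeq2 scaling (0.20), for Ldha over annotated transcripts (-0.0507), and for Atp5b over annotated transcripts (-0.63) and without incomplete and genomic reads (-0.33). Genes not past the threshold in the main comparison passed it with the other sign: over annotated transcripts Ckm (-0.13), H19 (-0.23), Des (-1.51), Nr1d1 (-1.78) and Thbs4 (-2.35), without incomplete and genomic reads Des (-1.21), Thbs4 (-1.70) and Car3 (0.15), under TMM Tpm2 (0.28) and Car3 (0.26), and under DESeq2 scaling Tpm2 (0.30) and Car3 (0.29). With the class of a chain taken from either library Acta1 (0.0347), Atp5b (-0.33), Des (-1.21), Thbs4 (-1.71) and Car3 (0.14) turned as well, while Aldoa, at -3.28 without incomplete and genomic reads, was at -0.03 and not past the threshold, which shows that the labels caused that value. The cause of the others was not tested. Over annotated transcripts 10 list sums moved by over 1 SD, those of the giant and membrane, endothelial and keratinocyte lists by over 1.5 times. Of 110 named genes with a test, 96 kept direction and side of the threshold under TMM, 68 at a coefficient of 0.2 and 29 at 0.4. The slow list's percentile fell to 41.5 over annotated transcripts. With matching on length it was 48.6, but 8 of its 10 tested genes remained there, with a median of 0.25 in place of 1.23. For that list the effect of length cannot be separated from that of the genes left out. Matching on length left 2 lists, mitochondrial and Schwann, outside the central 95%.

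Pearson's r was 0.885 without a read filter, 0.798 at 20 or more reads, 0.790 over annotated transcripts, 0.789 without incomplete and genomic reads, and 0.792 and 0.870 with pseudocounts of 0.1 and 10. The Myh4 share was 53.3% over annotated transcripts and 63.1% without incomplete and genomic reads, or 72.4% there with the class of a chain taken from either library. Isoform differences numbered 36 over all classes and 8 over annotated transcripts, with median main shares of 53.0% and 98.3%, and that median was 82.5% at 50 or more reads. With 1, then 5 or more reads, then sites within 5 bp, recurrence of unannotated combinations was 28.2%, 87.7% and 64.7% from replicate 1 and 42.0%, 94.9% and 78.1% from replicate 2; for chains with a new site it was 20.4%, 89.5% and 69.6%, and 24.1%, 89.7% and 76.3%. Without single-exon models the mean shares were 72.8% annotated, 0.0582% genomic, 0.0704% antisense and 0.0394% intergenic. The cause of these shifts was not tested. Leaving out each library gave 4.65 to 6.11 for the log2 of fast over slow, 77.0% to 88.1% for Myh4, 71.7% to 80.4% for the median main share, 64.5% to 66.1% for annotated reads, 9.10% to 14.7% for incomplete matches, 2.48% to 5.23% for unannotated combinations, 4.03% to 16.9% for new sites, 2.28% to 6.52% for genomic, 1.70% to 5.21% for antisense and 0.271% to 0.959% for intergenic reads. No paired analysis was possible because the series has 1 group. Few reads limit the test: 2-fold changes were recovered for 44.0% of simulated genes.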

Other observations

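The exon inclusion values, sex-linked genes and tests below were chosen after the results were seen, except the tests on slow fibre genes and on very short exons. Of 134 annotated alternative exons in 32 of the fixed isoform genes, with 20 or more spanning reads per library, 55 lay under 10% and 48 over 90% inclusion in both animals. Of the 55, 22 were missing through an unannotated intron from most spanning reads of both libraries, so their low values may come from read placement, for which the 477-fold excess among short exons is given below, but some of them were longer than 25 nt. The other 31, in 14 genes, differed by a median of 5.02 points, 23 of them by under 10 points, and 5 passed the two-sided Fisher exact test adjusted over the 134, 2 each in Tnnt3 and Myl1 and 1 in Neb. The 8 that differed by 10 points or more were 6 exons of Neb, the largest at 39.3% and 61.6% and alone of the 8 in passing the test, 1 of Nrap (71.4% and 52.4%) and 1 of Mbnl1 (15.2% and 3.85%). Atp2a1 included its 42-nt penultimate exon, the mark of the adult form, in 99.7% and 99.8% of spanning reads of replicates 1 and 2. Of the mutually exclusive 167-nt exons of Pkm, the one at chromosome 9, 59675029 to 59675195 was in 99.5% and 98.9% and the one at 59675568 to 59675734 in 0.442% and 1.06%. Tnnt3 used its pair of 41-nt exons side by side, the first in 61.0% and 54.9% and the second in 38.7% and 44.5%, a shift past the threshold in both. Mef2d carried its 135-nt exon in 83.5% and 84.6% and the alternative 138-nt exon in 16.5% and 15.4%, and Mef2c its 138-nt exon in 69.5% and 70.5%. Bin1 included its 72-nt exon in 37.1% and 35.4%, Nfix its 123-nt exon in 32.5% and 32.1%, and Myl1 its 28-nt exon in 26.9% and 21.9% against the 25-nt one in 73.7% and 77.8%.

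Y-linked genes were read in both libraries, in keeping with the male label: Eif2s3y had 59 and 40 reads, Ddx3y 34 and 25, Uty 22 and 5, and Kdm5d 4 and 5. In Schwann cell genes, the rise in replicate 2 lay outside annotated transcripts, as the report gives for Pmp22 and Mbp.

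Genes with long transcripts were lower and genes with short transcripts higher in replicate 2 (rho -0.594 over genes). Breakage of the mouse RNA before the spike-ins joined it would have made long genes fall further than long spike-ins, if broken pieces went uncounted. Gene counts summed all classes, incomplete and genomic reads included, so such pieces could still count for their gene. In the length range the spike-ins cover, genes differed between long and short by -0.51 and the spike-ins by -0.97. Genes thus lay 0.46 above the spike-ins (0.15 to 0.79) and not 0.50 below, the bound for breakage, so no added loss of long genes was seen there. Breakage cannot be excluded there, since broken pieces could still count and that bound was chosen after the results were seen. Gene ratios also carried a pseudocount, which draws them toward no change, and spike-in ratios did not. A step of library making or sequencing shared by both kinds of RNA may account for the trend, as the spike-ins followed it too (rho -0.768, permutation p = 0.00016 over 20). For the 7012 genes over 1124 nt, the length of the longest spike-in used, breakage cannot be told apart from such a step; 0 spike-ins over 2000 nt had 100 or more reads. A difference between the animals in slow fibre genes as a set did not pass the bound set beforehand, the upper end of the central 95%. The slow list stood at percentile 48.6 against lists matched on length and expression. That match held 8 of its 10 tested genes and left out Tnnt1 and Tnni1, both higher in replicate 2. It therefore cannot decide on such a difference. Leaving out 1 of its 8 genes with an annotated length gave percentiles from 15.5 to 97.2, all below that bound. The percentile was unsteady because members of the list go both ways, and single slow fibre genes were not tested for this.

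The main Atp2a1 transcript lacked the annotated 18-nt exon in 100% of spanning reads of both libraries. Loss of very short exons when reads are placed on the genome is a candidate explanation: coding exons of 25 nt or less were mostly missing through an unannotated intron 477 times as often as exons over 50 nt (43 of 146 against 11 of 17819). The 43 are not independent, since several lie in 1 gene, Tnnt3. Length alone did not decide the loss: 18-nt exons were kept in Atp2a2 by 290 of 310 and 88 of 95 spanning reads and in Trdn by 422 of 425 and 157 of 159. A splice variant of 1 parental allele stays open, since reads of an allele with the Atp2a1 exon would lose that exon if placement drops it. Short exons of Tnnt3, Tnni2 and Mrpl33 were likewise each missing from over 95% of spanning reads in both libraries. In Pdlim7 a 17-nt exon was missing through an unannotated intron from 97.1% and 98.0% of spanning reads. A 119-nt exon of Pdlim7 was missing in that way from 97.0% and 97.7%, which its own length does not explain. Reads that skipped the 17-nt and the 119-nt exon in that way were nearly equal in number, 545 and 546 in replicate 1 and 1042 and 1044 in replicate 2. Whether loss of the shorter exon accounts for both was not tested.

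Gapdh had 54 and 113 reads, few for an abundant glycolytic gene. Its reads may have been placed on near-identical copies: 23 annotated copies with 99% or more identity over 900 nt or more held 6620 and 5593 reads, 123 and 49.5 times those of Gapdh. Transcription common to Gapdh copies of every identity is argued against, because 44 copies of 95 to 99% identity held at most 0.121% as many reads per copy. Transcription of particular near-identical copies stays open, since silence of other copies cannot decide it. Reads were uneven among the near-identical copies: Gm12671 held 2386 and 919 and Gm10359 held 30 and 14, both at 100% identity.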
